A study of Mus musculus and Homo sapiens with 20 samples.

How the data were processed

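Chromatin accessibility was measured by ATAC-seq, in which the transposase Tn5 inserts sequencing adapters into open DNA, so that tags pile up where chromatin is accessible. There were 20 libraries. Of these, 8 came from HepG2, a human liver cancer cell line, at day 12, with 4 libraries labelled B2_minus and 4 labelled control. The other 12 came from mouse hepatocytes carrying a floxed Ahr gene, labelled 4 weeks, in 4 groups of 3. Those groups crossed control or B2_minus (vitamin B2, or riboflavin, deficiency per the labels) with Ad_Cont or Ad_Cre. Cre is the recombinase that removes DNA lying between loxP sites. The labels do not say whether replicates came from separate cultures or animals, so p-values measure only the spread between these samples, which may be technical.

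Groups were taken from the sample titles. For 8 of the 8 HepG2 libraries the name of the deposited file carried the opposite condition to the title, and for 0 of the 12 hepatocyte libraries. The HepG2 groups are therefore called the libraries labelled B2_minus and the libraries labelled control, and the direction of every HepG2 difference carries this doubt.

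The submitters' processing notes name Bowtie2 and HOMER, without versions or roles, and the builds hg38 and mm10. The aligner settings, read shifting, duplicate handling, peak thresholds and total reads are not given in the sources used here. Each deposited file listed the peaks of 1 library, nearly all 200 bp wide, with a whole-number count of tags per peak. That these values are unscaled counts was inferred from the values, since the files had no header. Each library had a lowest listed count of 6 to 8 tags, so a site below it was absent from the list rather than listed at 0. Replicates varied less than Poisson counting noise, as happens when at most 1 tag is counted per position and strand. High counts would then be compressed and differences at strong sites understated. For the same reason no pair of replicates could be singled out as 1 library listed again, and no files held identical values.

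The HepG2 lists held 253125 to 285530 peaks with 5705857 to 7856370 tags per library, after leaving out 0.131% of peaks on chromosome Y or unplaced sequences. The hepatocyte lists held 200698 to 281141 peaks with 3897632 to 5557678 tags, after leaving out 0.151%. These totals cover listed peaks only, and the sequencing depth is unknown. Peaks of all libraries of one cell system were merged where they overlapped by at least 1 bp, and a library's value in a region was its highest peak count there. This gave 500015 HepG2 regions, of which 141079 had a peak in all 8 libraries, and 642948 hepatocyte regions, of which 101575 had a peak in all 12. Tests on counts used only regions with a peak in every library, so a site lost entirely in 1 library was not tested, and fold changes at weak sites are bounded by the lowest listed count. Values printed per group are scaled tags, meaning counts divided by the library's TMM-adjusted size relative to the mean library.

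Each hepatocyte region was assigned to the nearest protein-coding gene body within 50 kb on GRCm38.p6, the assembly of mm10. The gene table gave no strand, so transcription start sites were not used. A region within 1 kb of either end of a gene is described as lying at a gene end. No human gene annotation and no genome sequence were used here, so HepG2 regions are given by hg38 coordinates alone, and the planned motif tests and HepG2 gene lists were not run.

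Counts were tested with edgeR 4.0.16 (TMM, quasi-likelihood F test) in R 4.3.3, with Benjamini-Hochberg adjustment and a threshold of 0.05. HepG2 was fitted with 2 groups. The 12 hepatocyte libraries were fitted together in 4 groups with 1 shared spread, and contrasts gave the B2_minus effect in each Ad arm, the Ad_Cre effect in each diet, and their interaction. Averages of both diet contrasts and of both Ad contrasts were added after it was seen that the arms moved together. Samples were not blocked by replicate number in the primary design. Which regions were called in every library of one group and in no library of the other was counted without a test. Totals per library were compared by exact two-sided permutation tests, for which 3 against 3 allows no p below 0.1 and 4 against 4 none below 0.0286.

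The form of the edgeR call was chosen after its first results were seen. The usual call, in which the variance cannot fall below Poisson, was run first and gave 4308 HepG2 calls and 17, 18, 0, 0 and 0 calls in the hepatocyte contrasts. Because replicates varied less than Poisson, the call without that bound (glmQLFit with legacy set to FALSE) was then adopted. The bounded counts are given beside the primary ones. Limma 3.58.1 on log2(tags + 1), which the design names for normalized values, gave 12845 HepG2 calls and 1087, 816, 7, 2 and 0 in the hepatocyte contrasts. The primary counts were 13339 and 1058, 1146, 6, 2 and 0. For B2_minus with Ad_Cre, limma called fewer regions and shared 69.8% of the primary calls. DESeq2 1.42.0 gave far fewer calls.

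Region names followed a rule fixed before the data were examined, with 1 change. The rule and the gene lists had been set by distance to transcription start sites. Gene bodies and gene ends replaced these because the gene table gave no strand. Per contrast the rule took up to 10 regions with the largest rise and 10 with the largest fall. These were taken among regions past the threshold whose groups did not overlap, at 1 region per gene and, in mouse, with a gene name. It added up to 4 called regions from each of 20 gene lists with a call, and in mouse always the regions nearest the ends of Ahr, Cyp1a1, Cyp1b1, Ahrr, Tiparp, Nqo1, Rfk, Flad1 and Slc52a2. Where no region passed, the 3 with the smallest p in each direction were taken. Genes with several called regions were picked out after the fact and are marked as such. The 20 lists cover AhR targets, riboflavin and flavin cofactors, mitochondrial flavoprotein dehydrogenases, fatty acid oxidation, fatty acid synthesis, cholesterol, glucose metabolism, the integrated stress response, NRF2 targets, xenobiotic and bile acid metabolism, hepatocyte identity, dedifferentiation and YAP targets, immediate early genes, cell cycle and p53 targets, inflammation, the circadian clock, and markers of stellate cells, Kupffer cells, endothelium and cholangiocytes. Symbols were matched for every list member but 1, of the 20 in the dedifferentiation and YAP list. Lists were tested with camera (limma) at a preset correlation of 0.01 and again with an estimated correlation.

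The edgeR procedure was tested on simulated counts with known changes at regions averaging at least 15 tags, drawn from the HepG2 fit (141079 regions) and from the hepatocyte fit (101575 regions). In the HepG2 simulation it recovered 62.7% of regions changed 1.5-fold, 94.0% of those changed 2-fold and 93.9% of those changed 3-fold, with 4 wrong calls among 171. In the simulation of B2_minus against control with Ad_Cont it recovered 43.3%, 83.6% and 92.4%, with 8 wrong calls among 154. With no change simulated it made 0 calls in either. Libraries were drawn independently with a variance below the mean, set near the fitted spread, so these results cannot show that this spread is right. Camera found the 1 shifted set of 20 and called 0 of the others.

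The alternatives were a lower bar for testing (a peak in at least 3 libraries, missing values set to the lowest listed count), library size from the tags in all listed peaks, quantile normalization, removal of the weakest 25% of regions, merging at 100 bp of overlap, the strongest 50000 peaks per library, the sum of peaks in a region, the replicate number as a block, pseudocounts of 1 and 4 with limma, DESeq2, a fit of only the groups compared, and leaving out each library in turn. Cyclic loess scaling, removal of the median log2 ratio of each 5 Mb bin in HepG2, the bounded edgeR call and the averaged contrasts were added after the data were seen. The planned use of a depth scaling by the authors was replaced by library size from listed tags, since the counts are unscaled. A change of sign in a value past no threshold either way was not counted as a reversal.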

Results

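In mouse hepatocytes with Ad_Cont, B2_minus libraries had more open chromatin inside Stab2, at the end of Gsta2 and inside Dmgdh than control libraries. Stab2 encodes a scavenger receptor best known from the endothelium of liver sinusoids, Gsta2 a glutathione transferase of detoxification, and Dmgdh dimethylglycine dehydrogenase, a mitochondrial enzyme that carries a riboflavin-derived cofactor. The region inside Stab2 (mm10 chromosome 10, 86872164 to 86872567) rose from 20.7 ± 2.06 to 44.1 ± 5.95 scaled tags (mean ± SD, n = 3 libraries per group; edgeR adjusted p 2.71e-05). At the end of Gsta2 (chromosome 9, 78347083 to 78347345) the signal rose from 25.6 ± 3.77 to 49.1 ± 6.13 (log2 fold change 0.93, SE 0.152; edgeR adjusted p 7.01e-05). Inside Dmgdh (chromosome 13, 93700691 to 93701124) it rose from 8.49 ± 1.28 to 21.1 ± 1.34 (edgeR adjusted p 0.00217). The 8.49 lies near the lowest listed counts of 6 to 8 tags. A second Dmgdh region 13 bp outside the gene's end rose by 0.60 on the log2 scale. Accessibility fell beside Ccl7, which encodes a chemokine that draws monocytes, where 25.9 ± 3.97 scaled tags became 10.5 ± 2.63 (chromosome 11, 82045483 to 82045795; edgeR adjusted p 0.00174). Of the 51 regions named with Ad_Cont, 2 stayed past the threshold with bounded edgeR, 2 with sums of peaks and 0 with DESeq2.

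With Ad_Cont, 3 genes of bile acid handling gained signal in B2_minus libraries. Cyp7a1, the first enzyme of the main route from cholesterol to bile acids, rose by 0.91 on the log2 scale inside the gene (chromosome 4, 6270558 to 6270861; edgeR adjusted p 0.00946). A region near Slc10a1, the bile acid importer of hepatocytes, rose by 0.61, and one in Cyp27a1, an enzyme of the alternative route, by 0.44. Genes of lipid synthesis with a rise were Me1 (1.02), Gpam (0.78), Dgat2 (0.73) and Scd1 (0.41). Irf1 and Socs3, a transcription factor of interferon responses and an inhibitor of cytokine signalling, lost signal nearby. The Irf1 region (chromosome 11, 53755037 to 53755396) fell from 23.6 ± 0.362 to 12.3 ± 0.497 scaled tags and the Socs3 region (chromosome 11, 117966474 to 117966863) from 29.9 ± 3.48 to 16.6 ± 1.18. Signal also fell near Tnfaip3, which restrains NF-kB, by 0.71 on the log2 scale.

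The largest other gains with Ad_Cont, with log2 fold changes from 1.09 to 1.30, lay near Ppm1b, Msantd4, Col27a1, Stip1, Ndufa4l2, Map3k19, Btbd7, Gm4606 and Mrtfb. The largest falls lay near Fxyd4 (-1.42), Parn, Cacna1a, Ebf1, Arhgap22, Mrgprd, Cxxc5, Ptcd2 and Lamc3 (-1.21). In B2_minus the Fxyd4 region held 6.6 ± 0.472 and the Mrgprd region 7.28 ± 0.89 scaled tags, at the lowest listed counts, so their SDs may be understated. Further genes with a region that rose were Gclc and Pir among NRF2 targets, Pfkp among glycolytic genes, Kdr among endothelial genes and Arntl of the clock. Some gains started near the lowest listed counts. In control, the Col27a1 and Ndufa4l2 regions each held 7.79 ± 0.957 scaled tags, and the Ppm1b and Gclc regions each 8.81 ± 0.163. Their SDs may be understated too. Regions near Hk2, Insig1, Gdf15, Dusp5, Col1a1, Flt1, Afp, Amotl2, Krt7 and Sox4 fell. By edgeR 430 regions were higher and 628 lower of 101575 tested, with a median log2 fold change of 0.68 among those higher and -0.87 among those lower. Groups did not overlap at 17.3% of tested regions, against 10% by chance. The count depends on the test and on how regions are chosen and valued. DESeq2 called 0, edgeR bounded at Poisson variance 17, and edgeR without any 1 of the 6 libraries from 264 to 562. With sums of peaks edgeR called 30, of which 12 were among the 1058, and with a peak in at least 3 libraries 27, of which 8 were.

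With Ad_Cre the same Stab2 region rose from 21.6 ± 0.639 to 43.8 ± 4.45 scaled tags (n = 3 per group; edgeR adjusted p 0.000224) and the same Gsta2 region from 26.5 ± 1.99 to 49.4 ± 2.63 (edgeR adjusted p 0.000224). A region near Ldha, the enzyme that interconverts pyruvate and lactate, rose from 41.2 ± 6.08 to 66.9 ± 4.66 (chromosome 7, 46838968 to 46839310). Regions near Hnf4a, a transcription factor that maintains hepatocyte identity, and in Slco1b2, a bile acid and drug importer, rose by 0.65 and 0.49 on the log2 scale. Irf1 again lost signal, from 22 ± 2.19 to 9.99 ± 0.426 (edgeR adjusted p 0.00619). Near Amotl2 and Sox4, a target of the growth regulator YAP and a transcription factor of progenitor cells, signal fell by 1.10 and 0.98 on the log2 scale. Spp1, Krt7 and Krt19, which mark bile duct and progenitor cells, fell by 1.17, 0.92 and 0.91. In B2_minus, Spp1 held 6.78 ± 0.482 and Krt19 7.06 ± 0.722 scaled tags. These lie at the lowest listed counts of 6 to 8 tags, below which nothing is listed, so their SDs may be understated.

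The largest other gains with Ad_Cre, with log2 fold changes from 1.00 to 1.14, lay near Rbpms, Gm42048, Neto2, Mical3, Myo1e, Kcnq3, Adh4, Myom1 and Glt28d2. The largest falls lay near Zfp366 (-1.34), Ncald, Gja5, Actn1, Txnrd2, Hivep3, Nav2, Gsdmc, Mrgprd and Strap (-1.25). The regions of Zfp366 and Ncald each held 6.78 ± 0.482 scaled tags in B2_minus, at the lowest listed counts, so their SDs may be understated. Among the gains, the Adh4 and Myo1e regions held 8.145 ± 0.547 and 8.30 ± 1.49 in control, also near those counts. Sardh, Scd1, Pfkp and Trf each had a region that rose, and Lrat and Fdft1 a region that fell. By edgeR 360 regions were higher and 786 lower, with medians of 0.58 and -0.86. Groups did not overlap at 17.5% of tested regions, against 10% by chance. DESeq2 called 0 regions, edgeR bounded at Poisson variance 18, and edgeR without any 1 of the 6 libraries from 350 to 582. With sums of peaks edgeR called 25, of which 10 were among the 1146, and with a peak in at least 3 libraries 32, of which 5 were.

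**Figure D1:**
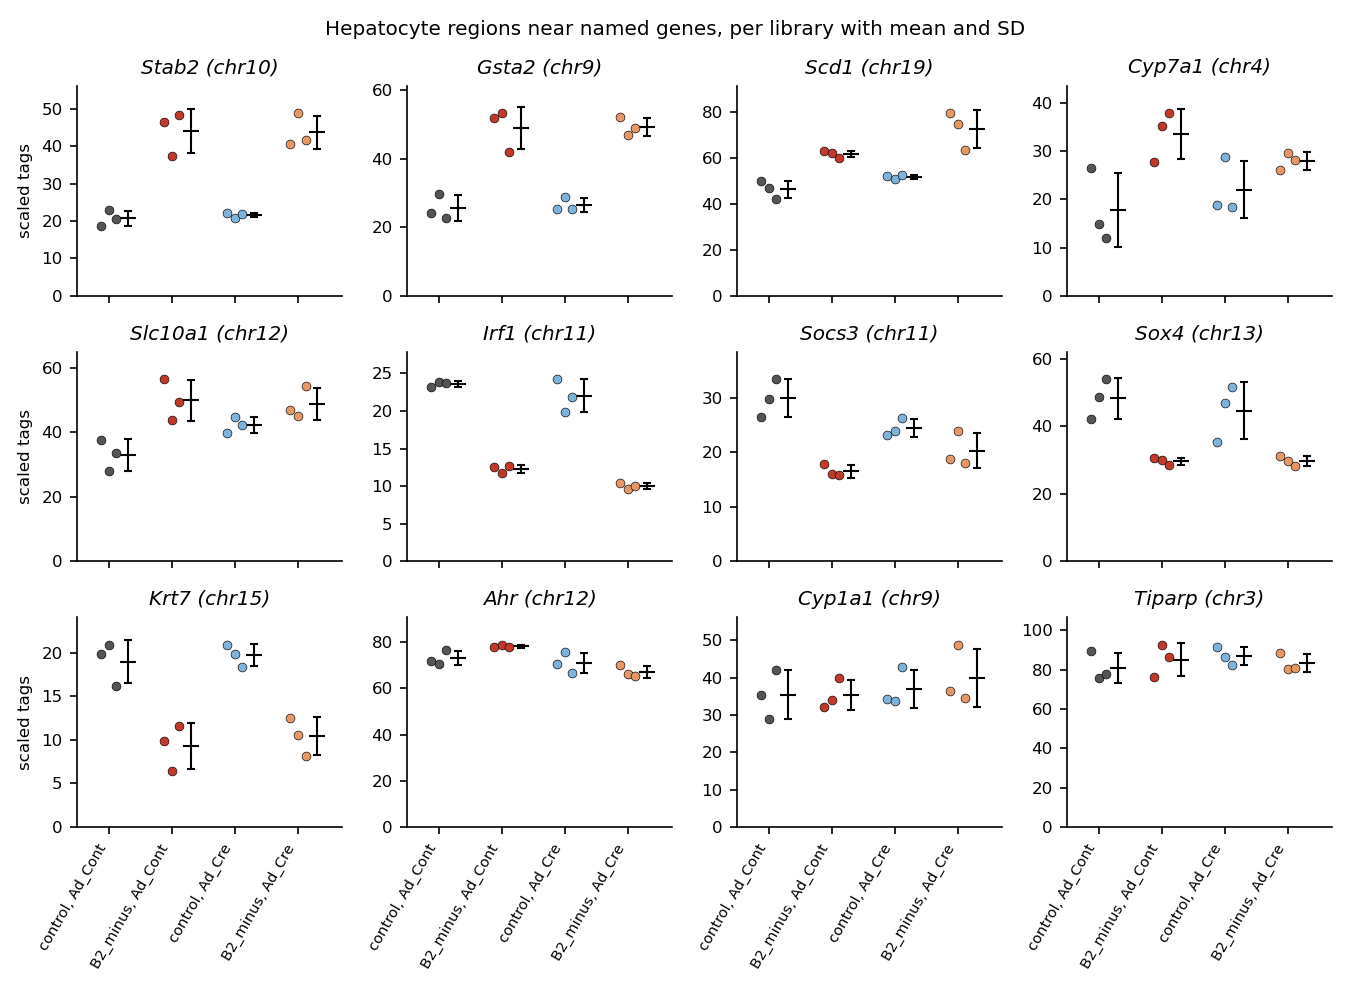
Scaled tags (vertical axis, from 0) in 12 hepatocyte regions, titled by nearest gene, for the 4 groups along the horizontal axis; points are libraries, bars the mean and SD of 3. Stab2 and Gsta2 are higher and Irf1 and Krt7 lower in B2_minus with either Ad construct, while the regions at Ahr, Cyp1a1 and Tiparp pass in no comparison.

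Between the Ad arms, changes in B2_minus libraries ran in parallel. Of the 198 regions called in both arms, 198 moved the same way, among them Stab2, Gsta2, Scd1 and one Pfkp region upward and Irf1, Sox4, Krt7 and Mrgprd downward. There were 46 shared gains against 1.52 expected if calls in the arms were independent, and 152 shared falls against 4.86. Of the 1058 regions called with Ad_Cont, 999 had the same sign with Ad_Cre. Across all tested regions, which are not independent replicates, the log2 fold changes of the arms, which share no library, had a Pearson r of 0.401 and a Spearman rho of 0.356. The r was 0.000923 in simulated counts without an effect. Those libraries were drawn independently, so this value does not exclude a preparation or batch that follows diet in both arms.

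**Figure D2:**
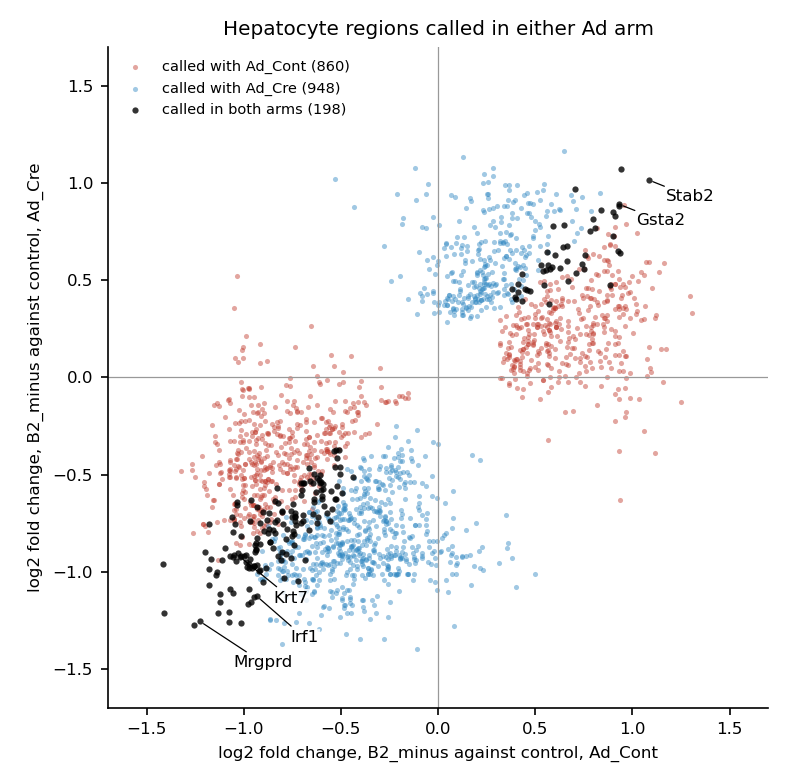
Log2 fold change of B2_minus against control with Ad_Cont (horizontal axis) and with Ad_Cre (vertical axis); each point is a region called in either arm. The 198 regions called in both, in black, lie only in the quadrants where both values have the same sign.

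Averaging both arms, a contrast added after their likeness was seen, gave 2484 higher and 3383 lower regions by edgeR. Stab2 led the gains (log2 fold change 1.05, SE 0.117; edgeR adjusted p 5.66e-11), followed by Mical3 (1.01), whose product oxidizes actin with a flavin cofactor, and Gsta2 (0.91). Larp4b, Babam2, Ffar4, Elk3, Dmgdh, Lyn and Vwa8 followed. The largest falls lay near Mrgprd (-1.24), Fxyd4, Trabd2b, Gsdmc, Castor2, Khdrbs2, Foxp4, Cuedc1, Vinac1 and H2ac6. Another region of Stab2 (chromosome 10, 86849574 to 86849906) fell by 0.95, so the gene's regions did not move as one. The bounded edgeR call gave 996 regions, DESeq2 46 and edgeR with sums of peaks 1469. A peak in at least 3 libraries gave 3275 higher and 889 lower, and library size from listed tags 9753 and 1998, so which direction prevails depends on these choices. A called region lay at a gene end in 10.7% of gains and 10.8% of falls, against 20.1% of the regions not called.

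The balance between gains and falls depended on the scaling and on which regions were tested. With TMM, 40.6%, 31.4% and 42.3% of calls were gains with Ad_Cont, with Ad_Cre and averaged. With library size from listed tags, all regions shifted upward in B2_minus by a median of 0.06, 0.14 and 0.10 on the log2 scale, and 67.9%, 89.4% and 83.0% of calls were gains. With regions that had a peak in at least 3 libraries and missing values at the lowest listed count, 55.6%, 56.2% and 78.7% of calls were gains, 3275 higher and 889 lower when averaged. Whether chromatin opened or closed on balance is therefore not decided, and the directions given for gene groups are relative to the typical region.

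Among the 20 gene lists, xenobiotic and bile acid metabolism shifted up and inflammation and the acute phase down relative to other regions in the averaged contrast (camera adjusted p 0.0123 and 0.0236). Of 143 regions near 20 genes of xenobiotic and bile acid metabolism, 12 rose and 2 fell over all regions tested, and 19 rose and 4 fell adjusted over the list alone. Cyp7a1, Slc10a1 and Sult2a8, a sulfotransferase, had regions that rose, and Nr1h4, the nuclear receptor for bile acids, one that fell by 0.44. Of 158 regions near 18 inflammatory genes, 2 rose and 17 fell, and adjusted over the list alone 3 rose and 19 fell. Regions that fell included those near Irf1 (-1.03), Lcn2 (-0.40), Cxcl1 (-0.71) and Tnfaip3 (-0.48). The inflammatory list had a median log2 fold change of -0.07, but 0.03 against 0.10 for other regions with library size from listed tags, where 13 of its regions were higher and 10 lower. Its camera adjusted p was 0.106 with regions limited to 10 kb. With an estimated correlation both lists passed (0.0334 and 0.0247), and fatty acid and triglyceride synthesis passed as well (0.0476, against 0.222 at the preset correlation).

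With TMM and the preset correlation, no other list passed in the averaged contrast. In fatty acid and triglyceride synthesis 12 regions rose and 1 fell, with the same counts adjusted over the list alone. They included Scd1, the desaturase that makes monounsaturated fatty acids, with Me1 and Fads1 rising and Lpin2 falling. Dedifferentiation and YAP targets had 2 rises and 19 falls (3 and 23 adjusted over the list alone; camera adjusted p 0.117), with falls near Sox4, Amotl2 and Krt7. That list had a median of -0.03, which became 0.06, with 15 regions higher and 13 lower, under library size from listed tags. Mitochondrial flavoprotein dehydrogenases had 4 rises and 1 fall, the same adjusted over the list alone (camera adjusted p 0.0664, and 0.0462, passing, with library size from listed tags), with Sdha rising and Prodh falling besides Dmgdh. Riboflavin and flavin cofactor metabolism had 0 called regions of 31 by edgeR, also adjusted over the list alone, and a camera adjusted p of 0.645. AhR targets had 6 rises and 3 falls (6 and 3 adjusted over the list alone; camera adjusted p 0.353), with Gsta2 rising, Lrat falling and Itpr1 regions moving both ways.

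Hepatocyte identity had 10 rises and 3 falls (6 and 2 adjusted over the list alone), with gains near Tdo2, Hnf4a, Cps1 and Fgb. Fatty acid oxidation had 5 rises and 3 falls (4 and 1 adjusted over the list alone), with Hadh and Acaa2 rising and Ppargc1a, a coactivator of mitochondrial genes, falling by 0.76. Cholesterol synthesis had 4 rises and 1 fall (1 and 1 adjusted over the list alone), with Sc5d and Mvk rising and Insig1 falling. Glucose metabolism had 10 rises and 5 falls (10 and 5 adjusted over the list alone), with gains near Pfkp, Ldha and Pcx. The Ldha region was 55.3 ± 3.45 scaled tags in control and 56.9 ± 4.76 in B2_minus with Ad_Cont (n = 3), so its averaged gain came from the Ad_Cre arm; the interaction did not pass there. NRF2 targets had 4 and 4 (4 and 4 adjusted over the list alone), with Pir rising and Akr1b8, Akr1c13 and Fth1 falling. The integrated stress response had 1 rise and 4 falls, the same adjusted over the list alone, the falls near Gdf15, Phgdh, Vldlr and Cebpb. That list's median of 0.01 and its camera direction, down, differed in sign. The clock had 7 rises and 5 falls (4 and 4 adjusted over the list alone), with Rora regions moving both ways. Immediate early genes had 3 and 5 (2 and 2 adjusted over the list alone), and cell cycle genes 0 and 2, both near Ccnd1 (0 and 0 adjusted over the list alone). With library size from listed tags the balance turned to gains in the integrated stress response (11 higher, 2 lower), immediate early genes (17 and 1) and cell cycle genes (7 and 0).

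None of the lists of markers of other liver cells passed with TMM. Stellate cell markers had 0 rises and 3 falls, near Col1a1 and Lrat (0 and 6 adjusted over the list alone; camera adjusted p 0.0664, and 0.0462, passing, with library size from listed tags). Kupffer cell markers had 1 fall, near Laptm5, also adjusted over the list alone, but 4 higher and 1 lower with library size from listed tags. Cholangiocyte markers had 1 rise and 6 falls, near genes such as Krt7, Krt19 and Spp1 (2 and 6 adjusted over the list alone), but 5 higher and 4 lower with that scaling. Endothelial markers had 6 rises and 3 falls (8 and 4 adjusted over the list alone), rising at a pair of Stab2 regions and falling at Flt1. The inflammatory and YAP lists lost regions with TMM in the same libraries in which the stellate and cholangiocyte markers lost regions.

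By arm, lists passed only with Ad_Cont. There, xenobiotic metabolism rose (camera adjusted p 0.0390; 3 rises and 0 falls, 7 and 3 adjusted over the list alone) and inflammation fell (0.0390; 0 rises and 3 falls, 1 and 10 adjusted over the list alone). Neither passed with regions limited to 10 kb (0.0772 and 0.193) or with library size from listed tags (0.0645 each), and with an estimated correlation only inflammation did (0.0250). With Ad_Cre 0 lists passed, the lowest camera adjusted p being 0.0605 for xenobiotic metabolism and for mitochondrial flavoproteins.

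**Figure D3:**
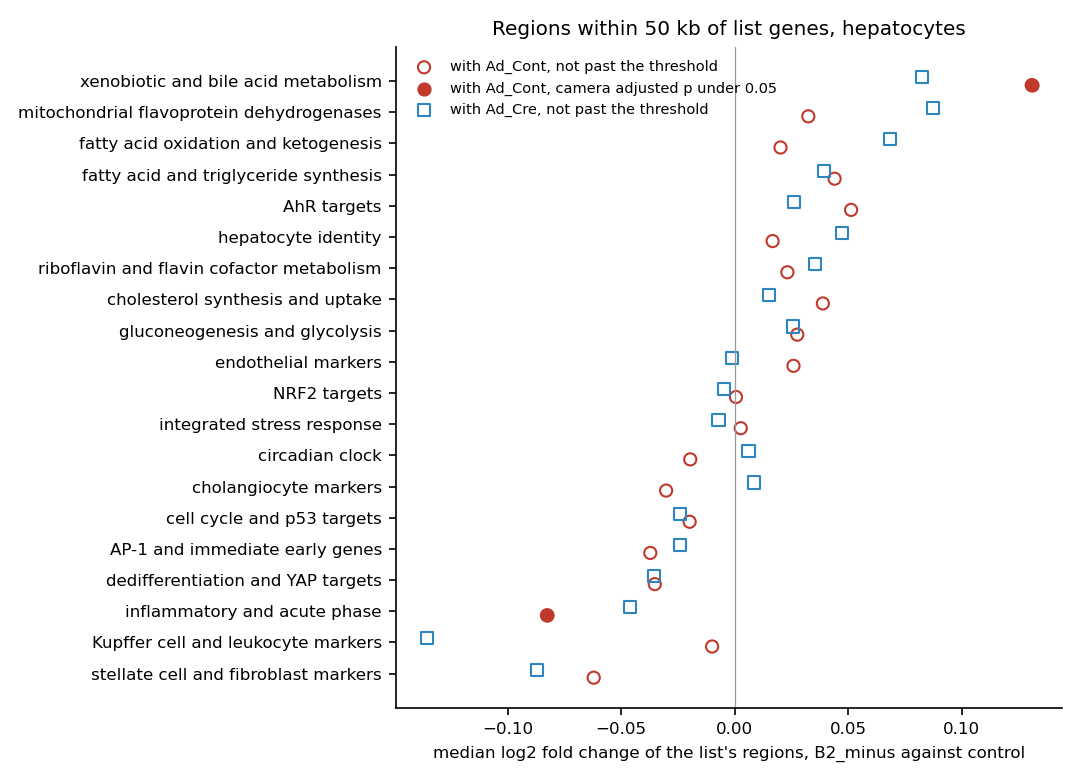
Median log2 fold change of the regions within 50 kb of each list's genes (horizontal axis), B2_minus against control, for 20 lists (vertical axis) and both Ad arms; filled symbols passed camera at an adjusted p of 0.05. Xenobiotic and bile acid metabolism lies to the right in both arms and inflammation to the left, though with library size from listed tags its median lies above 0 with Ad_Cre.

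Few regions were called between Ad_Cre and Ad_Cont, though the second principal component (10.8% of variance) separated their libraries. In control libraries, signal rose inside Gabbr2 (1.31 on the log2 scale), a neurotransmitter receptor gene, and inside Traf3 (0.69), an adaptor of immune signalling. With Ad_Cont the Gabbr2 region held 8.11 ± 0.469 scaled tags, near the lowest listed counts. Signal fell inside Pml, which organizes nuclear bodies, near Raph1, and at the end of Ybx3, by 0.81, 0.71 and 0.57. The remaining called region, 103526 bp from Btg1 and named after its values were seen, fell by 0.79. In B2_minus libraries a region beside Smc3, a cohesin subunit, rose from 20.6 ± 2.79 to 38.7 ± 4.49 scaled tags (n = 3; edgeR adjusted p 0.0170), and one near Cd180 fell from 35.8 ± 1.57 to 16 ± 9.73 (edgeR adjusted p 0.00530). EdgeR thus called 6 regions in control and 2 in B2_minus, of 101575 each, with 7941 and 7406 at an unadjusted p under 0.05. The bounded edgeR call and DESeq2 called 0 in each. Sums of peaks gave 2 and 6 calls and a peak in at least 3 libraries 16 and 15, but 0 of the 6 and 2 named regions passed in either, and 0 of the 6 passed with loess. Leaving out 1 library gave 0 (without Ad_Cre replicate 3) to 4 calls in control, and in B2_minus 0 (without replicate 1 of either Ad group) to 5. Groups did not overlap at 12.4% and 12% of regions, against 10% by chance, and 0 gene lists passed in either.

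Averaging both diets, a contrast also added later, gave 49 higher and 48 lower regions with Ad_Cre by edgeR, and 0 with DESeq2 or the bounded call. In the primary edgeR fit 10027 regions (9.87%) had an unadjusted p under 0.05, so few calls do not show that few regions changed. With sums of peaks edgeR called 1, and with a peak in at least 3 libraries 14, of which 0 were among the 97 in either. None of the 20 regions named here passed in any of these 4 settings. Leaving out 1 library gave 29 (without control Ad_Cre replicate 3) to 101 regions. The count moved by over 1.5 times without 8 of the 12 libraries, the exceptions being control Ad_Cont replicate 3, B2_minus Ad_Cont replicate 2, control Ad_Cre replicate 1 and B2_minus Ad_Cre replicate 1. A region beside Cyp2e1, a cytochrome of alcohol oxidation, rose by 0.81 (chromosome 7, 140763426 to 140763766; edgeR adjusted p 0.0326), and the smallest adjusted p, 0.000652, was inside Habp4. Other gains lay near Lect2, Megf11, Ddhd1, Atf7ip, Myo5b, Wasl, Bfsp1 and Sp1. Falls lay near Nfkb1 (-0.89), a subunit of NF-kB, Foxo1 (-0.65), a transcription factor of fasting, and Abhd3, Syne2, Abcb9, Mup20, Sptbn1, Ankrd17, Ppat and Dlc1. With library size from listed tags 342 regions passed, 32 of them higher.

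The region nearest the end of Ahr itself (chromosome 12, 35534948 to 35535212) held 73.1 ± 3.17 scaled tags in control with Ad_Cont and 70.9 ± 4.50 with Ad_Cre (n = 3; edgeR adjusted p 0.951). In B2_minus it held 78.2 ± 0.571 and 67.1 ± 2.46 (edgeR adjusted p 0.573). The position of the floxed segment is not given in the labels, so these values do not measure deletion. Regions at the ends of the AhR targets Cyp1a1, Cyp1b1, Ahrr, Tiparp and Nqo1, and of Rfk, Flad1 and Slc52a2, which make flavin cofactors or import riboflavin, passed in no hepatocyte comparison.

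For the interaction, whether the B2_minus change differed between Ad_Cre and Ad_Cont, edgeR called 0 of 101575 regions, with 5221 (5.14%) at an unadjusted p under 0.05, and DESeq2 and the bounded call 0. The smallest p values, none passing, lay at Ybx3, Smc3 and Tnfrsf11a in one direction and at Ggcx, Trim14 and Mnt in the other (edgeR adjusted p 0.578 each). All 20 lists had a camera adjusted p of 0.966. What size of difference between the arms this test could find was not simulated.

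In HepG2, regions are given by position because no human gene annotation was used here. The largest gain in libraries labelled B2_minus lay on chromosome 2, 20430954 to 20431266 (hg38), where 11.8 ± 2.56 scaled tags became 41.1 ± 7.2 (n = 4 per group; log2 fold change 1.82, SE 0.182; edgeR adjusted p 3.07e-16). On chromosome 22, 20551491 to 20552679, 17 ± 9.25 became 59.6 ± 7.07 (edgeR adjusted p 6.09e-23). The largest fall lay on chromosome 12, 31278845 to 31279267, from 27.5 ± 2.07 to 8.85 ± 1.13 (log2 fold change -1.63, SE 0.216; edgeR adjusted p 8.20e-10). A region on chromosome 21, 33059578 to 33059871, fell by 1.51. The 10 named gains rose by 1.51 to 1.82 on the log2 scale and the 10 named falls fell by 1.37 to 1.63. All of these directions carry the doubt that the file names give the opposite condition to the titles.

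Of 141079 HepG2 regions tested, edgeR called 7761 higher and 5578 lower in libraries labelled B2_minus, with median log2 fold changes of 0.54 and -0.61. Groups did not overlap at 12.7% of tested regions, against 2.86% by chance. The bounded edgeR call gave 2807 higher and 1501 lower, DESeq2 1052 and 405, edgeR with sums of peaks 4071 and 2679, and edgeR with a peak in at least 3 libraries 3982 and 1348. The share higher was 58.2% in the first of these counts, 74.7% in the last and 53.04% with the strongest 50000 peaks. If the file names rather than the titles are right, these are shares lower in B2_minus. Called regions made up 6.06% (chromosome X) to 11.2% (chromosome 18) of those tested per chromosome.

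**Figure D4:**
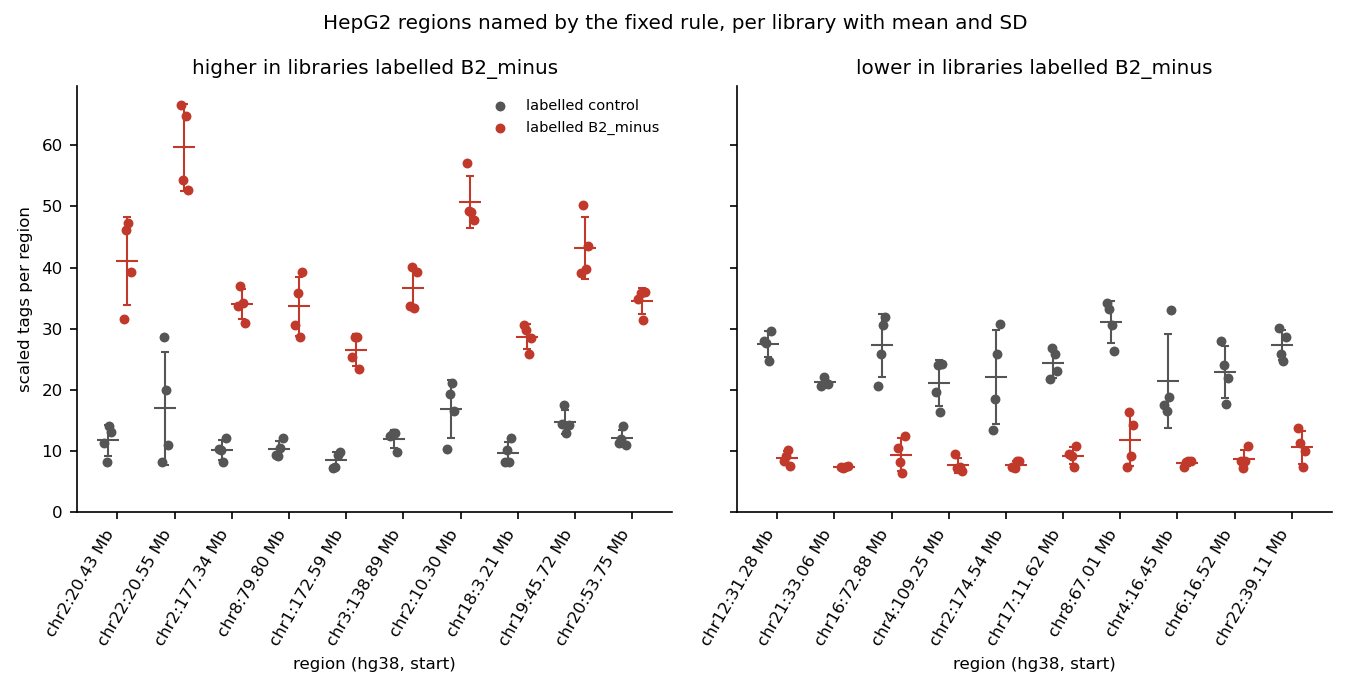
Scaled tags (vertical axis, from 0) in the 20 HepG2 regions named by the fixed rule, by position on hg38 (horizontal axis), in libraries labelled control and B2_minus; points are libraries, bars the mean and SD of 4. Groups do not overlap in any of the 20, since the rule took only such regions.

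Principal components of log2 tags separated the groups in both systems. In HepG2 the first component (31.3% of variance) placed libraries labelled B2_minus at 43.2 to 61.7 and those labelled control at -60.9 to -47.7. On the second (13.3%) control replicate 3 lay at 86.0 and the others between -37.4 and 8.53. In hepatocytes the first component (18.7%) separated B2_minus from control and the second (10.8%) Ad_Cre from Ad_Cont.

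**Figure D5:**
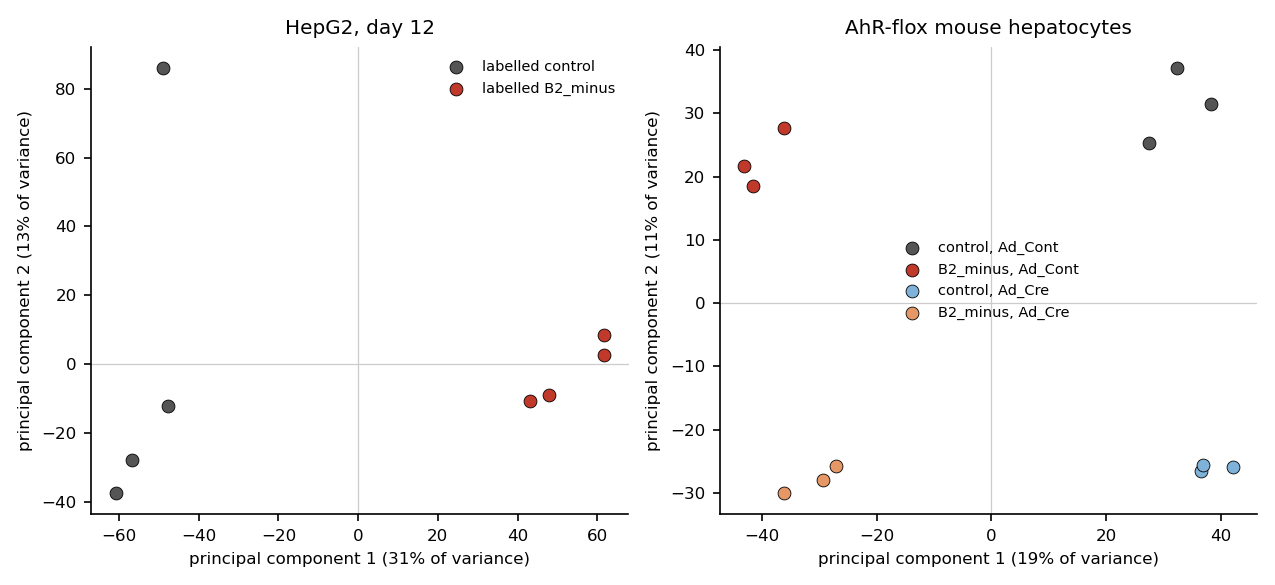
Principal components 1 and 2 of log2 scaled tags for 8 HepG2 libraries (left) and 12 hepatocyte libraries (right); axes give the percent of variance and each point is a library. Groups separate on the first component in each system, and the Ad arms separate on the second in hepatocytes.

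Some regions were called in every library of one group and in none of the other. In HepG2 there were 1022 such regions in libraries labelled B2_minus and 868 in those labelled control, 1890 together. With Ad_Cont there were 2149 in B2_minus and 1647 in control, 3796 together, and with Ad_Cre 1429 and 3018, 4447 together. Ad_Cre against Ad_Cont gave 2898 and 1017 in control, 3915 together, and 1499 and 1303 in B2_minus, 2802 together. Other splits of the same libraries gave up to 1020 in HepG2, 2781 and 3137 for B2_minus with Ad_Cont and with Ad_Cre, and 4043 and 2653 for Ad_Cre in control and in B2_minus. In control a wrong split thus gave more than the real one. There the real split gave 4473 and the highest other 4452 with merging at 100 bp, and 646 and 467 with the strongest 50000 peaks. Without any 1 library each of these counts rose by over 1.5 times. Such counts depend on how many peaks each list holds. Control libraries with Ad_Cre held 271297 ± 14895.8 peaks and B2_minus libraries 226048 ± 15675.2 (exact two-sided permutation p 0.1, the smallest that 3 against 3 allows). The share of those peaks at a gene end was 14.4% ± 0.727 in control and 15.9% ± 0.582 in B2_minus (exact permutation p 0.1). Of 14 such exact permutation tests of peaks, tags and gene-end share, none passed (lowest adjusted p 0.533). With so few libraries none could have passed after adjustment, so this does not show that the groups were alike.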

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

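The tests by other groupings of the samples and by cyclic loess scaling were chosen only after the results they test were seen; the tests of 5 Mb bins and of cell type markers were written before. For bins and loess the share of the same calls was computed first, and the ratio of counts, which the bound of 80% names, after it. Among 46 HepG2 groups of 4 libraries, 4 held a library far from its 3 partners by Dixon's criterion, against 2.3 by chance. On chromosome 3, 138891175 to 138891545, control replicate 4 had 9.9 scaled tags and its partners 12.4 to 12.9 (gap over range 0.833). On chromosome 2, 10297941 to 10298368, the library labelled B2_minus replicate 1 had 57 and its partners 47.7 to 49.3 (0.834). On chromosome 4, 16449974 to 16450357, the library labelled B2_minus replicate 1 had 7.39 against 8.21 to 8.37 (0.836), and control replicate 4 had 33 against 16.6 to 18.8 (0.866). These values lie in regions that were chosen because their groups did not overlap. No explanation was tested for the values.

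HepG2 libraries labelled B2_minus and control differed at 13339 regions. Of the 35 splits of the 8 libraries only 1, the real one, called as many, and the highest other called 1, which argues against chance. Removing the median log2 ratio of each 5 Mb bin left 96.42% of the count, with 89.2% of the same calls, against copy-number or clonal differences over long stretches as the whole cause. Cyclic loess scaling left 99.93% of the count, with 88.8% of the same calls, against a trend with signal strength. A response to the condition may remain, as a hypothesis, but the labels and file names disagree on which libraries are B2_minus, and culture, batch or passage was not recorded and stays untested.

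Hepatocyte B2_minus libraries differed from control at 5867 regions averaged over both Ad arms. Of 60 relabellings of diet within the arms, only 1, the real one, called as many, and the highest other called 505. This argues against chance only if the libraries of the 2 Ad arms are independent. If each preparation was split between the arms, its libraries should be relabelled together. Too few splits would then remain for a share under 0.05. Cyclic loess scaling left 86.16% of the count but 77.8% of the same calls, which lies under that bound, so a trend with signal strength may account for part of the calls. A different share of non-parenchymal cells cannot be told apart from a change within hepatocytes: endothelial regions moved up and stellate and Kupffer regions down, but none of the 3 lists passed camera (lowest adjusted p 0.06639; with library size from listed tags stellate markers passed, at 0.0462), and Lrat, Krt7 and Spp1 also stand in other lists. Like changes in 2 arms that share no library leave a response to B2 deficiency possible, as a hypothesis. Animal, preparation or batch is not given in the labels, may follow diet in both arms and stays untested.

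Hepatocyte Ad_Cre and Ad_Cont differed at 97 regions averaged over both diets, where 1 of 60 relabellings, the real one, called as many and the highest other called 6, which argues against chance. Whether loss of AhR, the Cre enzyme or a difference between the Ad preparations lies behind these regions was not tested. For single contrasts the 10 splits of 6 libraries are too few for a share under 0.05: 1 of 10 called as many with Ad_Cont (1058, highest other 1), 1 of 10 with Ad_Cre (1146, highest other 0), 1 of 10 for Ad_Cre in control (6, highest other 4) and 1 of 10 for Ad_Cre in B2_minus (2, highest other 1). For the interaction the real count was 0, so that 60 of 60 relabellings of diet called as many by construction, and this comparison says nothing; the highest called 237, for which no cause was tested.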

How the results depend on the processing

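Loess scaling, the bounded edgeR call, 5 Mb bins and the averaged contrasts were chosen after results were seen. Counts below run in the order HepG2; B2_minus with Ad_Cont and with Ad_Cre; Ad_Cre in control and in B2_minus; averaged B2_minus; averaged Ad_Cre. Where no cause is given, the cause was not tested. DESeq2 called 1457, 0, 0, 0, 0, 46 and 0 regions, and bounded edgeR 4308, 17, 18, 0, 0, 996 and 0. The strongest 50000 peaks, with fewer regions tested, gave 3322, 264, 213, 3, 0, 1511 and 8, and sums of peaks 6750, 30, 25, 2, 6, 1469 and 1, with 1 for the interaction. A peak in at least 3 libraries gave 5330, 27, 32, 16, 15, 4164 and 14, with 9 for the interaction. Library size from listed tags gave 4559 with Ad_Cre, 27 and 1 for Ad_Cre against Ad_Cont, and 11751 and 342 averaged. Merging at 100 bp gave 12 and 0 for Ad_Cre against Ad_Cont, and loess 0 in control. Quantile scaling, removal of the weakest regions, limma with either pseudocount and a fit of only the groups compared moved no count by over 1.5 times.

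Without 1 library, counts ran from 9542 to 12028; 264 to 562; 350 to 582; 0 to 4; 0 to 5; 4148 to 5070; and 29 to 101. Every 1 of the 6 libraries moved the counts with Ad_Cont and with Ad_Cre by over 1.5 times, where fewer libraries give less power. The interaction had 0 to 1, the 1 without control Ad_Cre replicate 2. Regions called in one group only numbered 991, 940, 1039, 646 and 553 among the strongest 50000 peaks, and from 3174 to 3688, 7923 to 10634, 8849 to 13089, 8496 to 12097 and 6692 to 7996 without 1 library, since fewer libraries must then share a peak.

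Of named regions past the threshold, DESeq2 kept 17 of 17 with a value in HepG2, 0 of 51 with Ad_Cont, 0 of 38 with Ad_Cre and 8 of 83 averaged, and library size from listed tags 20 of 20, 46 of 51, 36 of 38 and 78 of 85. Bounded edgeR kept 20 of 20, 2 of 51, 7 of 38 and 37 of 85. Without any 1 library 20 of 20, 19 to 37 of 51, 21 to 28 of 38 and 74 to 83 of 85 stayed. Sums of peaks kept 20 of 20, 2 of 51, 3 of 38 and 45 of 85, and a peak in at least 3 libraries 20 of 20, 2 of 51, 3 of 38 and 48 of 85. Of 20 named for averaged Ad_Cre, 0 stayed in these 2 settings, with DESeq2 or with bounded edgeR, and 8 to 16 without 1 library. Over named regions and single gene lists in all settings, 5631 values stayed on the same side of the threshold. These include values that passed in neither setting, so 5631 does not measure how many passing values were kept. A further 1182 fell short of the threshold in the same direction, and 3 newly passed, each a gene list. The remaining 1 reversed: the Pfkp region on chromosome 13, 6647688 to 6648169, at -0.15 with sums of peaks. Lists passing were 2 with Ad_Cont (1 with an estimated correlation, 0 within 10 kb, 0 with library size from listed tags) and 2 averaged (1 within 10 kb, 4 with library size from listed tags). With the replicate number as a block the counts were 13041, 1051, 1173, 6, 2, 5836 and 106. Over all other groups, 0 of 8 HepG2 and 5 of 12 hepatocyte libraries correlated best with their own number. Within a diet, deviations from the group mean of same-number libraries of the 2 Ad arms correlated at 0.00149 to 0.0123. Those of different number correlated at -0.0135 to 0.00395. These values are small, but a preparation shared between the Ad arms is not excluded. The block joins equal numbers across diets as well, so it does not settle this. The lowest listed count limits what weak regions can show, and total depth is unknown. Motif tests and HepG2 gene lists were not run.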

Other observations

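The genes with many called regions were counted after the results were seen. In the averaged contrast, a growth factor gene and adhesion genes lost signal at many of their regions. At Pdgfb, which encodes a platelet-derived growth factor, 8 of 8 tested regions between 80011718 and 80037981 on chromosome 15 fell, by 0.47 to 0.97 on the log2 scale. At the integrin genes Itga3 and Itgb6, 8 of 13 and 6 of 14 regions fell. Near Ccl2, a chemokine that draws monocytes and lies in the same cluster as Ccl7, 6 of 15 fell. Glis3, a transcription factor of bile duct and pancreas development, had 7 of 15 falling. At Sfi1, 20 of 38 regions fell, all between 3146778 and 3200052 on chromosome 11, by 0.17 to 0.62. These lie in 1 stretch and may not be separate changes. Without Sfi1, 3363 of the 3383 lower calls remain. No filter for hard-to-map sequence was applied, and whether mapping plays a part at this stretch was not tested.

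Near Cited2, a regulator of transcription coactivators, 6 of 15 regions rose by 0.22 to 0.48, and near Scd1 5 of 13 rose by 0.27 to 0.45. Robo1 and Tm4sf4 had 5 rising regions of 24 and 22 tested and Prkce and Rbpms 5 of 52 and 56, with 0 falling. Mical3 had 5 rising and 1 falling of 51, and Mrtfb 5 and 2 of 38. Called gains lay near 1750 genes and called falls near 2064.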
